A study of Homo sapiens with 6 samples.

How the data were processed

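RNA was sequenced from SW1990 cells, a human pancreatic cancer line, that carried either a non-targeting shRNA or an shRNA against LRRC8A, with 3 libraries per group and 6 in all. Per the labels' protocols, the hairpins were expressed from the lentiviral vector pLKO.1, transduced cells were kept by puromycin selection as stable lines, RNA was taken with Trizol, and libraries were made with a stranded mRNA kit. The series describes the 3 libraries of a group as biological replicates, and the labels put all 6 in 1 batch, so no split by batch could be made. If the libraries of a group came from the same stable line, the p-values measure spread between its cultures and not between separate transductions. The labels name 1 LRRC8A hairpin, and the hairpin sequences are not given in the sources used here.

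Per the submitters' processing notes, fastp 0.23.2, HISAT2 2.2.1 and StringTie 2.2.3 were used, and the genome builds GRCh38 and mm10 are both named without a role. The deposited table held, for each library, whole-number read counts per gene, FPKM values (fragments scaled by gene length and depth) and TPM values (transcript shares scaled to a fixed sum). The program that counted the reads and its strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. The deposited counts were raw, with library totals of 37052641 to 42937612. The deposited FPKM and TPM values were normalized by the authors for gene length and depth, and TPM was read only to check its sums. All 20345 genes of the deposited table were of the protein-coding class, so non-coding transcripts were not analysed here. Gene symbols were assigned by Ensembl identifier, 18988 from HGNC names in the table and 14 from a reference table. Other genes took the gene name of the table, and identifiers were kept where a symbol was ambiguous. The table's gene coordinates equalled those of GENCODE 29 (GRCh38) for 100 of the 19511 genes in both, so positions are given from GENCODE 29 and not from the table.

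The test used the counts, as set out before the data were examined. Genes were filtered with filterByExpr, library sizes were scaled by TMM factors, and the groups were compared with the quasi-likelihood F-test of edgeR 4.0.16 (robust, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over 13551 genes and a threshold of 0.05. The model had no term for the replicate number, since nothing in the labels says that equal numbers share a culture or a day. Levels are counts scaled to library size with TMM factors (CPM), as mean ± SD, and the SE of a log2 fold change is its size divided by the square root of the F statistic. Single values were also compared by an exact two-sided permutation test, which with 3 against 3 libraries cannot give a p below 0.1.

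Before the data were examined, 36 gene lists were fixed, covering the volume-regulated anion channel, ion and osmolyte transport, growth, stress, metabolic, adhesion and differentiation programmes, pancreatic cancer subtypes, and markers of leukocytes, fibroblasts, endothelium and exocrine or endocrine pancreas. The table held 944 of their 960 genes. Lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 33 lists. Each list was tested again with a correlation estimated from the libraries, and with fry, which asks whether the genes of a list move one way on balance.

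The genes named in the text were chosen by a rule fixed before the data were examined. It takes LRRC8A to LRRC8E. It adds the 10 higher and 10 lower genes with the largest log2 fold change among those past the threshold, without overlap between the groups and with a mean of at least 200 reads in the higher group. From each list it takes the 2 to 4 members with the smallest adjusted p, or at most 2 where no member passed. Genes named outside this rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here.

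Alternatives were a replicate block, each library left out in turn, DESeq2 size factors within edgeR, DESeq2 1.42.0, no filter on low counts, an adjusted p of 0.01, and a minimum absolute log2 fold change of 1. Limma with a trend was also run on log2(FPKM + 1) of genes with at least 1 FPKM in at least 3 libraries. Its pseudocount (0.1 and 0.5), filter (none, or at least 5 FPKM), scaling (rescaled to an equal sum, quantile normalization, TMM factors) and trend were then changed singly. A setting without genes that hold a given 7-base word in the 3′ UTR was added after seeing the data. It was not a new fit: those genes were dropped from the main fit, the p-values of the rest were adjusted again, and camera was rerun. The other 9 of the 10 splits of the libraries into 3 and 3 were fitted in the same way.

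The words of 7 bases were scanned in the annotated 3′ UTRs (GENCODE 29, at least 50 bases) of 12966 tested genes. Each word held by at least 30 genes was scored by the mean of the log2 fold change over its SE, after a regression on UTR and transcript length, GC content and expression, against 1000 shuffles of the genes. The scan recovered 20 of 20 implanted words in simulated values, each shifting its genes by 0.5 SD. Smaller shifts were not simulated. The edgeR test was tested on simulated data with the real means, library sizes and dispersions of this comparison, in which 200 genes were changed. Of 13427 genes tested there, it recovered 30.9% of the genes changed by 0.25 on the log2 scale, 74.2% of those changed by 0.5 and 86.4% of those changed by 1, with 8 false calls among 135. In 10 simulated comparisons without any change it called at most 6 genes, and camera called 0 lists. Genes were drawn independently in all these simulations, so their figures do not cover correlation between genes.

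No library was left out and none was counted as a duplicate: chi-square per degree of freedom between pairs of libraries was 6.38 to 21.3 within groups, far above sampling noise, and 13.6 to 22.4 between groups.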

Results

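Gene expression was measured by RNA-seq in SW1990 cells, a human pancreatic adenocarcinoma line, to ask what a lower level of LRRC8A changes in the transcriptome. LRRC8A is the obligatory subunit of the volume-regulated anion channel (VRAC), which releases chloride and organic osmolytes when cells swell. Control cells carried a non-targeting shRNA and the others an shRNA against LRRC8A, with 3 libraries per group that the series describes as biological replicates. The control libraries held 37318300, 37052641 and 37565017 counts in replicates 1 to 3, and the LRRC8A shRNA libraries 42937612, 37295187 and 37434891. Counts were detected for 15385 to 15593 genes per library. Mitochondrially encoded mRNAs took 5.19% ± 0.378 (SD, n = 3) of the counts in controls and 5.36% ± 1.04 (SD, n = 3) in LRRC8A shRNA libraries.

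LRRC8A mRNA (ENSG00000136802; GRCh38, chromosome 9, 128882112 to 128918039, plus strand) was lower in each LRRC8A shRNA library than in every control library. The 3 control libraries held 3012, 2725 and 2667 LRRC8A counts, and the 3 LRRC8A shRNA libraries 1782, 1411 and 1556. The level fell from 75.6 ± 5.01 CPM to 40.1 ± 2.03 CPM (SD, n = 3 each), a log2 fold change of -0.92 with an SE of 0.06 and an edgeR adjusted p = 1.46e-08 (Benjamini-Hochberg). This is 47.0% less mRNA, with a 95% confidence interval of 42.6% to 51.0%. The exact permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries allow. LRRC8A overlaps KYAT1 on the opposite strand, and reads of the overlap could have been counted for either gene.

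None of the 4 partner subunits that assemble with LRRC8A into channels passed the test. The log2 fold changes were -0.10 (SE 0.05) for LRRC8B, 0.11 (SE 0.09) for LRRC8C, -0.13 (SE 0.06) for LRRC8D and -0.19 (SE 0.10) for LRRC8E. Their edgeR adjusted p-values were 0.371, 0.585, 0.313 and 0.330, and 0 of the 4 had an unadjusted p under 0.05. LRRC8C and LRRC8D share sequence with an annotated read-through gene, so their counts are uncertain. Among the VRAC subunits as a list, 1 of 5 fell, and 1 also when adjusted over the list alone. The list holds LRRC8A itself, so its camera result (lower, adjusted p = 0.0340, but adjusted p = 0.599 with an estimated correlation) in part restates the knockdown, and the 4 partners alone are too few for the test. Without control replicate 2 or 3, or without LRRC8A shRNA replicate 1 or 2, the camera adjusted p was 0.0820, 0.0871, 0.0727 and 0.111.

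**Figure D1:**
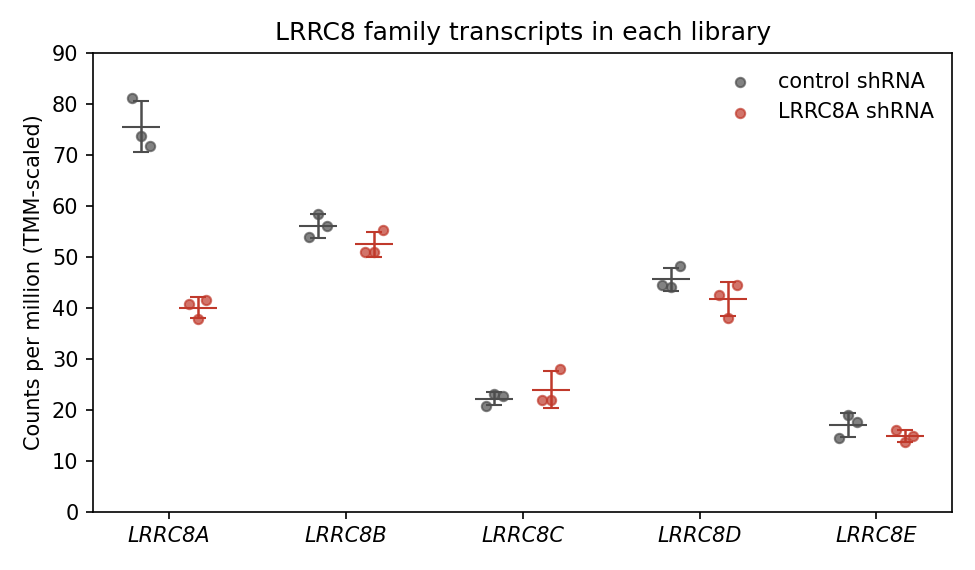
CPM (TMM-scaled, vertical axis) of the 5 LRRC8 genes in each of the 6 libraries; points are libraries, and bars are the group mean with SD (n = 3). LRRC8A lies at 40.1 CPM on average in the LRRC8A shRNA libraries against 75.6 CPM in controls, while the groups of the other genes lie close together.

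Across the transcriptome 590 of 13551 tested genes changed (4.35%), 240 higher and 350 lower in the LRRC8A shRNA libraries (edgeR, Benjamini-Hochberg adjusted p under 0.05). A list below with a share of changed members near 4.35% holds no more than the tested genes as a whole. Most changes were small. The median size among changed genes was 0.27 on the log2 scale, which is 1.21-fold, and 534 genes (90.5%) changed by less than 1.5-fold. Only 22 changed genes reached an absolute log2 fold change of 1, of which 3 were higher and 19 lower. At an unadjusted p of 0.05, 2475 genes passed, against 678 that chance would give. The 3 values of each group lay apart from those of the other in 3199 genes (23.6%, where chance gives 10%), and in all 590 changed genes. The first principal component held 26.2% of the variance and separated the groups, and the second held 22.4%. The number of changed genes was 273, 246 and 346 without control replicate 1, 2 or 3 and 318 without LRRC8A shRNA replicate 1. Limma on FPKM values called 182 genes.

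**Figure D2:**
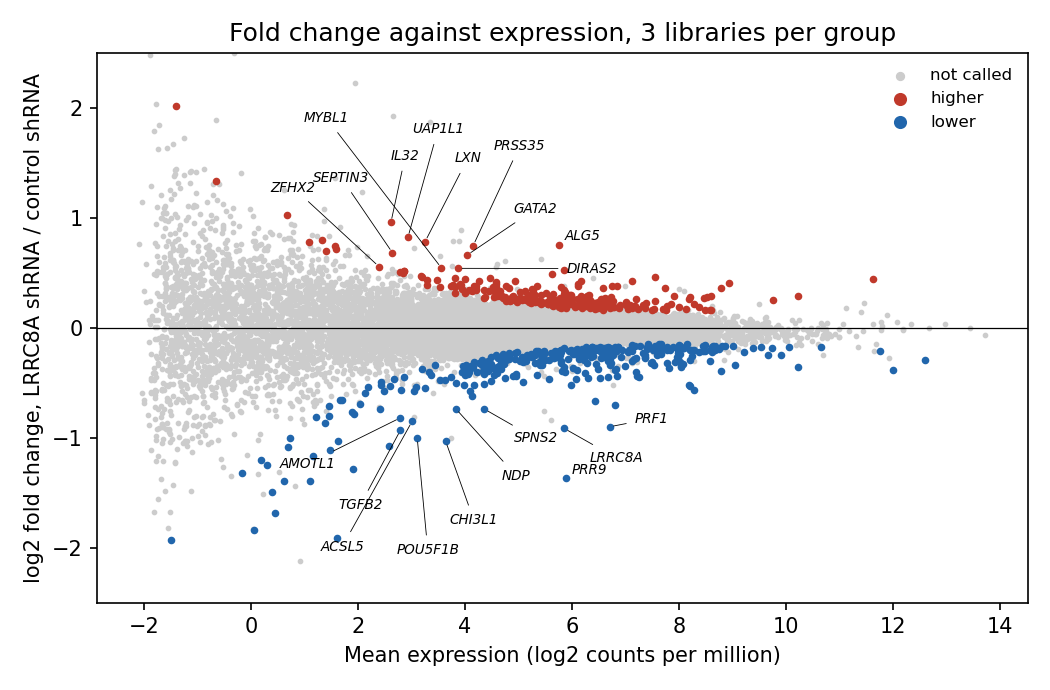
Log2 fold change of LRRC8A shRNA over control shRNA libraries (vertical axis) against mean expression in log2 CPM (horizontal axis), 1 point per tested gene. The 240 higher genes are red, the 350 lower genes blue, and the genes named by size of change are labelled; 6 genes that were not called lie outside the axis limits.

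PRR9, a proline-rich gene of the epidermal differentiation complex, fell from 85.1 ± 4.08 to 33.0 ± 2.58 CPM (log2 fold change -1.37, SE 0.06, edgeR adjusted p = 6.25e-11). CHI3L1, a secreted glycoprotein of the chitinase family, fell by 1.03 on the log2 scale (SE 0.11, edgeR adjusted p = 1.57e-05). TGFB2, a TGF-beta ligand, fell by 0.93 (SE 0.13, edgeR adjusted p = 0.000346), and PRF1, which encodes the pore-forming protein perforin, fell by 0.90 (SE 0.05, edgeR adjusted p = 9.26e-09). ACSL5, a long-chain acyl-CoA synthetase, fell by 0.85, the junctional protein gene AMOTL1 by 0.82, the sphingosine-1-phosphate exporter gene SPNS2 by 0.74 and the Wnt receptor ligand gene NDP by 0.74. POU5F1B, a retrogene copy of POU5F1, fell from 11.4 ± 0.663 to 5.74 ± 1.47 CPM (SD, n = 3 each) and is nearly identical to its parent, so its counts are uncertain. ACSL5 and SPNS2 overlap genes on the opposite strand, and AMOTL1 and NDP hold the word GTGTCAC, described with the higher genes, in the 3′ UTR. In GRCh38, PRR9 lies on chromosome 1 (153217584 to 153219317), CHI3L1 on chromosome 1 (203178931 to 203186749), TGFB2 on chromosome 1 (218346235 to 218444619) and PRF1 on chromosome 10 (70597348 to 70602775).

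Among genes that rose, IL32, a proinflammatory cytokine, went from 4.10 ± 0.472 to 7.97 ± 1.24 CPM (SD, n = 3 each; log2 fold change 0.96, SE 0.15, edgeR adjusted p = 0.000687). UAP1L1, related to an enzyme of UDP-GlcNAc synthesis, rose by 0.82 (SE 0.13), and LXN, a carboxypeptidase inhibitor, by 0.78 (SE 0.12). ALG5, a glucosyltransferase of N-glycan assembly, rose to 67.6 ± 3.34 CPM (SD, n = 3; log2 fold change 0.76, SE 0.06, edgeR adjusted p = 8.06e-07). The others were PRSS35 (0.75), the cytoskeletal GTPase gene SEPTIN3 (0.68), the transcription factor genes GATA2 (0.66), ZFHX2 (0.56) and MYBL1 (0.54), and the RAS-like GTPase gene DIRAS2 (0.54). ZFHX2 did not pass in 5 of the 6 fits that left out 1 library, where its edgeR adjusted p reached 0.116 (without control replicate 2). In GRCh38, IL32 lies on chromosome 16 (3065297 to 3082192), ALG5 on chromosome 13 (36949775 to 37000261) and GATA2 on chromosome 3 (128479427 to 128493185). LXN, ALG5 and ZFHX2 overlap genes on the opposite strand. The annotated 3′ UTRs of LXN, ALG5, SEPTIN3 and DIRAS2 hold the word GTGTCAC, which was found in 31.1% of the 235 higher genes with an annotated 3′ UTR and in 9.35% of the 12387 such genes that were not called.

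Of 29 genes of RAS-ERK output, 9 fell, 3 rose and 17 did not pass; adjusted over the list alone, 13 fell and 4 rose. The EGF receptor ligand genes EREG and AREG fell by 0.52 (SE 0.06) and 0.41 (SE 0.07), the ERK phosphatase gene DUSP6 by 0.34 (SE 0.06) and the cyclin gene CCND1 by 0.25 (SE 0.04), with edgeR adjusted p-values of 0.000548, 0.00261, 0.00317 and 0.00299. The 3 that rose, named after their values were seen, were SPRY4 (0.26), ETV5 (0.26) and DUSP4 (0.30), feedback or transcription factor genes of the pathway. The list was lower by camera (adjusted p = 0.000669, but adjusted p = 0.599 with an estimated correlation). DUSP4, SPRY4 and ETV5 passed in 1, 3 and 2 of the 6 fits that left out 1 library. DUSP6 holds the word GTGTCAC in its 3′ UTR, and CCND1 and ETV5 overlap other genes.

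In the basal-like pancreatic cancer subtype list, 6 of 18 members fell and 0 rose, and 8 fell when adjusted over the list alone. KRT17, a basal keratin, fell by 0.37 (SE 0.05, edgeR adjusted p = 0.000417), the glucose transporter gene SLC2A1 by 0.36 (SE 0.06, edgeR adjusted p = 0.000938) and the cancer-testis gene LEMD1 by 1.39 (SE 0.25, edgeR adjusted p = 0.00337). LEMD1 stayed under the mean of 200 reads required of genes named by size of change, so its fold change is imprecise. The list was lower by camera (adjusted p = 3.76e-06, but adjusted p = 0.599 with an estimated correlation). In the classical pancreatic cancer subtype list, 1 of 18 fell, the tetraspanin gene TSPAN8 (-0.29), and the list did not pass (camera adjusted p = 0.271). It was 1 as well when adjusted over the list alone. Of 31 genes of epithelial junction and differentiation, 4 fell and 0 rose, against 5 lower and 1 higher adjusted over the list alone. Among them were the simple-epithelium keratins KRT18 (-0.38, SE 0.05) and KRT8 (-0.29, SE 0.06) and the membrane protease gene ST14 (-0.19, SE 0.04). That list did not pass (camera adjusted p = 0.156). KRT8 and KRT18 overlap on opposite strands, TSPAN8 overlaps LGR5, and ST14 and KRT8 passed in 3 and 5 of the 6 fits that left out 1 library (KRT8 at an edgeR adjusted p of 0.0702 without control replicate 3).

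Genes of TGF-beta signalling, adhesion and matrix fell in small numbers. Of 24 TGF-beta targets, 4 fell and 0 rose, and adjusted over the list alone 4 fell and 1 rose. The matrix protein gene TGFBI fell by 0.41 (SE 0.05, edgeR adjusted p = 0.000176), beside TGFB2 and the collagen IV gene COL4A2 (-0.26). The list was lower by camera (adjusted p = 0.00728, but adjusted p = 0.599 with an estimated correlation), and not without LRRC8A shRNA replicate 3 (adjusted p = 0.0922), on genes of at least 5 FPKM (0.0718) or after quantile normalization of FPKM (0.0670). Of 23 YAP/TAZ targets 3 fell, TGFB2, the ectonucleotidase gene NT5E (-0.30) and TGFBR2 (-0.24), with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.109, and 0.0179 without LRRC8A shRNA replicate 2). Of 28 integrin and focal adhesion genes 2 fell, ITGB5 (-0.32) and ITGB4 (-0.22), and 4 adjusted over the list alone (camera adjusted p = 0.113, and 0.00843 without LRRC8A shRNA replicate 2). Among 23 collagens, laminins and matrix enzymes, LAMB2 rose (0.27) while the plasminogen system genes PLAUR (-0.32) and PLAT (-0.58) and COL4A2 fell. Adjusted over the list alone, 4 fell and 1 rose (camera adjusted p = 0.483). Of 19 mesenchymal transition genes 1 fell, and 3 fell when adjusted over the list alone (camera adjusted p = 0.407). COL4A2 passed in 3 of the 6 fits that left out 1 library, PLAT in 4, and PLAUR and TGFBR2 in 5 (edgeR adjusted p up to 0.0529 for PLAUR without control replicate 1 and 0.0694 for TGFBR2 without control replicate 2). COL4A2 and ITGB4 overlap genes on the opposite strand.

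Of 40 genes of G2/M and mitosis, 4 rose and 0 fell, 11 rose when adjusted over the list alone, and 37 had a positive log2 fold change. The ubiquitin-conjugating enzyme gene UBE2C rose by 0.24 (SE 0.05, edgeR adjusted p = 0.00599), the spindle genes TACC3 by 0.22 and TPX2 by 0.18, and the cytokinesis gene ANLN by 0.20. The list was higher by camera (adjusted p = 8.52e-07, but adjusted p = 0.599 with an estimated correlation). Of 39 genes of G1/S and DNA replication, the helicase subunit gene MCM6 rose (0.26, SE 0.05), which was also 1 adjusted over the list alone; its 3′ UTR holds the word GTGTCAC. That list did not pass (camera adjusted p = 0.729, and 0.00754 without control replicate 2). Of 27 p53 targets 5 fell and 0 rose, and adjusted over the list alone 11 fell and 1 rose. PLK2, a stress-induced kinase, fell by 0.32 (SE 0.05, edgeR adjusted p = 0.000591), the exonuclease gene AEN by 0.28 (SE 0.04, edgeR adjusted p = 0.000754), the death receptor gene FAS by 0.25 and PHLDA3 by 0.23; the last of the 5, named after its value was seen, was FDXR (-0.29). The p53 list was lower by camera (adjusted p = 9.74e-06, but adjusted p = 0.599 with an estimated correlation). Of 33 apoptosis regulators 2 fell, the BH3-only gene PMAIP1 (-0.35, SE 0.05) and FAS, and 2 adjusted over the list alone (camera adjusted p = 0.811). PHLDA3, FAS and FDXR each passed in 1 of the 6 fits that left out 1 library, TPX2 and ANLN in 2, TACC3 in 3 and MCM6 in 5 (edgeR adjusted p = 0.0550 without control replicate 1). FAS and ANLN overlap genes on the opposite strand.

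Of 32 genes of ribosome biogenesis and MYC targets 4 fell and 0 rose, 12 fell when adjusted over the list alone, and 29 had a negative log2 fold change. The nucleolar protein gene NOP56 fell by 0.22 (SE 0.04, edgeR adjusted p = 0.00324), MYC by 0.20 (SE 0.04, edgeR adjusted p = 0.00933), RRP12 by 0.18 and MYBBP1A by 0.15. The list was lower by camera (adjusted p = 2.44e-06, but adjusted p = 0.599 with an estimated correlation). Of 43 cytosolic ribosomal protein genes 3 fell, RPS25 (-0.17), RPS9 (-0.16) and RPSA (-0.17), 3 also adjusted over the list alone, and 42 had a negative log2 fold change. The ribosomal list was lower by camera (adjusted p = 7.09e-05, but adjusted p = 0.599 with an estimated correlation), and not after quantile normalization of FPKM (adjusted p = 0.318). MYC passed in 4 of the 6 fits that left out 1 library, RPS9 in 2, and RRP12, MYBBP1A, RPS25 and RPSA in 1 each. RPS9, RPS25 and MYBBP1A overlap genes on the opposite strand.

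Of 18 genes of the heat shock response 5 rose and 0 fell, and adjusted over the list alone 11 rose and 1 fell. The co-chaperone genes FKBP4, DNAJA1, HSPH1 and DNAJB1 rose by 0.22 (SE 0.05), 0.28 (SE 0.06), 0.28 (SE 0.06) and 0.17 (SE 0.05), and AHSA1, named after its value was seen, by 0.18. The list was higher by camera (adjusted p = 0.000819, but adjusted p = 0.599 with an estimated correlation). Of 30 NRF2 and glutathione genes 6 rose and 2 fell, against 9 and 2 adjusted over the list alone. UGDH, which makes UDP-glucuronate, rose by 0.27 (SE 0.05, edgeR adjusted p = 0.00342), the ferritin light chain gene FTL by 0.44 (SE 0.09) and the glutathione reductase gene GSR by 0.19 (SE 0.04). The export pump gene ABCC2 fell by 0.28 (SE 0.06), as did PGD (-0.16), named after its value was seen. The NRF2 list was higher by camera (adjusted p = 0.0140, but adjusted p = 0.631 with an estimated correlation), and not without control replicate 3 (adjusted p = 0.0604) or LRRC8A shRNA replicate 1 (0.127) or 2 (0.0779). Among 34 lysosome and autophagy genes the autophagy receptor gene SQSTM1 alone rose (0.29, SE 0.06), also adjusted over the list alone. That list was higher by camera (adjusted p = 0.0153, but adjusted p = 0.599 with an estimated correlation), and not without control replicate 3 (adjusted p = 0.0767) or LRRC8A shRNA replicate 2 (0.105). FKBP4 and UGDH hold the word GTGTCAC in the 3′ UTR. DNAJB1, AHSA1 and SQSTM1 overlap genes on the opposite strand. ABCC2 and FKBP4 passed in 5 and 4 of the 6 fits that left out 1 library, UGDH in 6, and each other gene of these lists named here in at most 3.

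Of 16 genes of hyperosmotic response and osmolyte transport 3 fell and 1 rose, against 3 and 2 adjusted over the list alone. The glutamine transporter gene SLC1A5 fell by 0.30 (SE 0.04, edgeR adjusted p = 0.000548), SLC2A1 as above, and the large neutral amino acid transporter gene SLC7A5 by 0.22 (SE 0.05, edgeR adjusted p = 0.0122). SLC38A2, an osmotically regulated amino acid transporter gene, rose by 0.19 (SE 0.05, edgeR adjusted p = 0.0460). The list did not pass (camera adjusted p = 0.923, direction down, with a median of 0.01 and a mean of 0.00 on the log2 scale). Of 25 genes of cell volume and anion transport, the kinase gene WNK1 alone rose (0.16, SE 0.04); adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.563). Of 35 genes of the integrated stress response 5 fell and 0 rose, and 7 fell when adjusted over the list alone (camera adjusted p = 0.0921). They were the transcription factor gene ATF3 (-0.29), SLC7A5, the cationic amino acid transporter gene SLC7A1 (-0.20), PCK2 (-0.15) and, named after its value was seen, GARS1 (-0.17). SLC38A2, WNK1, SLC7A1, PCK2 and GARS1 each passed in 1 of the 6 fits that left out 1 library, SLC7A5 in 3 and ATF3 in 5 (edgeR adjusted p = 0.0655 without control replicate 3). SLC1A5 and PCK2 overlap genes on the opposite strand, and ATF3 holds the word GTGTCAC.

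Of 41 members of the type I interferon list 5 fell and 0 rose, 10 fell when adjusted over the list alone, and 34 had a negative log2 fold change. OASL fell by 0.26 (SE 0.05, edgeR adjusted p = 0.0129), IFIT2 by 0.20, the RNA sensor gene RIGI by 0.17, IFI6 by 0.37 and, named after its value was seen, IFI27 by 0.35. The list was lower by camera (adjusted p = 0.000128, but adjusted p = 0.599 with an estimated correlation). Of 20 antigen presentation genes the peptidase gene ERAP2 alone fell (-0.27), also adjusted over the list alone (camera adjusted p = 0.427). Of 27 NF-kB and inflammatory cytokine genes IL32 alone rose, also adjusted over the list alone (camera adjusted p = 0.162). IFIT2 and ERAP2 passed in 3 of the 6 fits that left out 1 library, OASL and IFI6 in 2, and RIGI and IFI27 in 1. RIGI holds the word GTGTCAC, and IFIT2 overlaps LIPA on the opposite strand.

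Metabolic lists held few changed genes. Of 41 nuclear-encoded oxidative phosphorylation genes NDUFA2 alone fell (-0.28, SE 0.07), also adjusted over the list alone, and 34 had a negative log2 fold change. That list was lower by camera (adjusted p = 0.00670, but adjusted p = 0.599 with an estimated correlation), and not without control replicate 2 (adjusted p = 0.0886) or LRRC8A shRNA replicate 3 (0.114), or after quantile normalization of FPKM (0.188). In cholesterol and sterol synthesis 0 of 25 genes passed, 2 fell when adjusted over the list alone, and TM7SF2 (-0.24) and SREBF2 (-0.15) had the smallest adjusted p. The sterol list was lower by camera (adjusted p = 0.0357, but adjusted p = 0.739 with an estimated correlation). It did not pass without LRRC8A shRNA replicate 1 (adjusted p = 0.197) or 2 (0.169) or after quantile normalization of FPKM (0.0723), and its direction turned without control replicate 3 (adjusted p = 0.700). In fatty acid synthesis and lipid desaturation 0 of 22 passed and 3 fell when adjusted over the list alone, with SCD at -0.28 and ACSL1 at -0.19. The fatty acid list lay at the threshold (camera adjusted p = 0.05002, not passed), and passed without control replicate 1 (0.0154) or 2 (0.0132) or LRRC8A shRNA replicate 3 (0.0473). It passed in 15 of 19 other settings of the fit (0.0132 to 0.0499), so its call rests on the setting. In glycolysis and hypoxia 34 genes were tested, SLC2A1 fell and the neuronal enolase gene ENO2 rose (0.45, SE 0.08; GTGTCAC in its 3′ UTR), with the same counts adjusted over the list alone (camera adjusted p = 0.517). Of 13 mitochondrially encoded mRNAs MT-ND3 alone fell (-0.19), also adjusted over the list alone. The list had a camera adjusted p = 0.923, and without LRRC8A shRNA replicate 3 was lower (0.00794). NDUFA2, TM7SF2 and ENO2 overlap other genes, and NDUFA2 and MT-ND3 passed in 2 and 1 of the 6 fits that left out 1 library.

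In the unfolded protein response of the endoplasmic reticulum 0 of 28 genes passed, with 0 adjusted over the list alone (camera adjusted p = 0.923, direction up, while fry gave down); CALR was at -0.16 and HERPUD1 at 0.14. Among replication-dependent histones 0 of 12 passed, with 0 adjusted over the list alone (camera adjusted p = 0.858, direction up, with a median and a mean of -0.04); H1-2 was at 0.21 and H4C8 at 0.32. Of 5 tested leukocyte markers, CORO1A, also expressed in epithelial lines, fell (-0.23), which was 1 adjusted over the list alone (camera adjusted p = 0.355), and it passed in 0 of the 6 fits that left out 1 library. Of the fibroblast and stellate cell markers 3 were tested and 0 passed, with ACTA2 at 13.7 ± 0.628 CPM in controls and 12.8 ± 1.61 CPM in LRRC8A shRNA libraries. Of the endothelial markers 4 were tested and 0 passed, with EGFL7 at 23.8 ± 1.84 and 20.1 ± 2.13 CPM. Of the acinar and endocrine markers 3 were tested and 0 passed, with PRSS1 at 15.8 ± 1.66 and 11.9 ± 2.08 CPM. Adjusted over the list alone, EGFL7 and PRSS1 were lower and 0 fibroblast markers passed. These last 3 lists had too few tested members for camera.

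**Figure D3:**
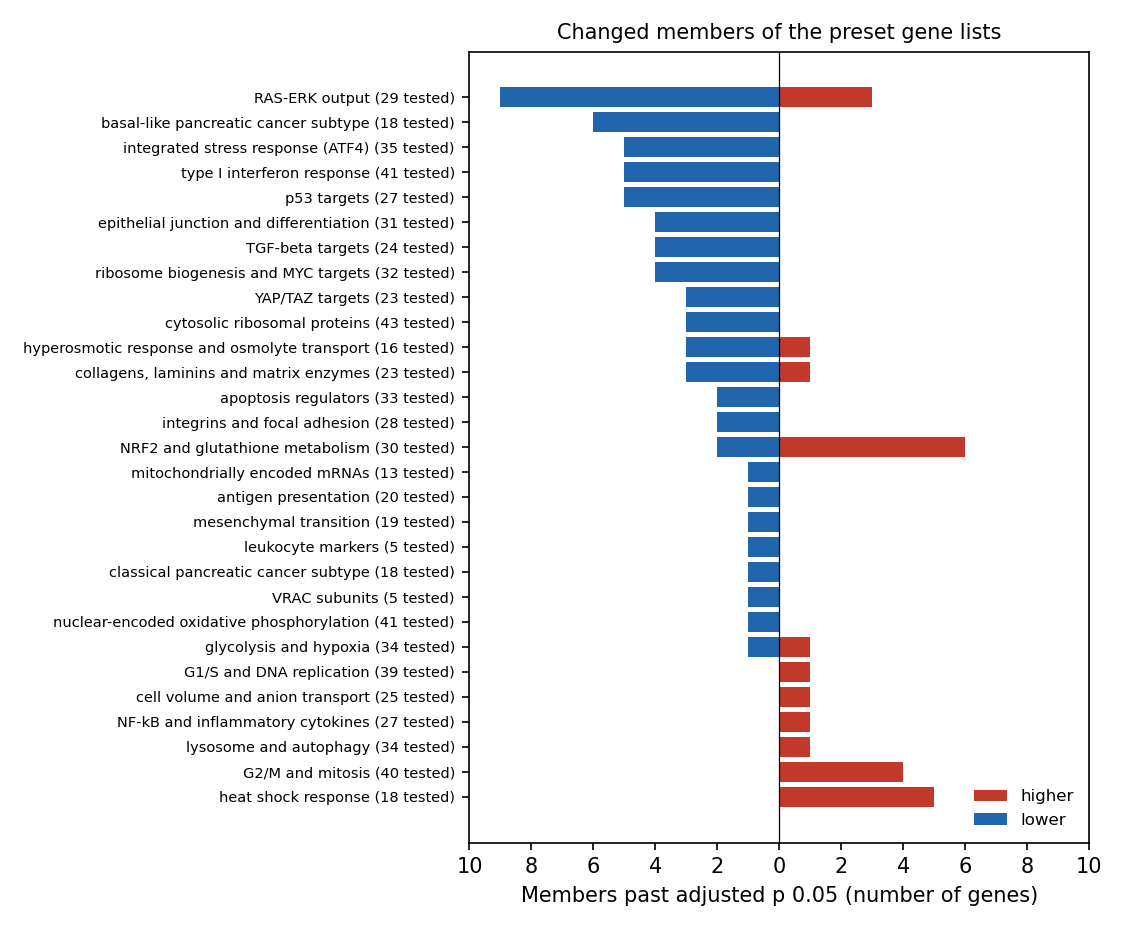
Number of members of each preset gene list past an edgeR adjusted p of 0.05 (horizontal axis), higher in red to the right and lower in blue to the left; lists without a changed member are not drawn. RAS-ERK output held the most changed members, 9 lower and 3 higher.

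By camera with the preset correlation 14 of 33 lists passed, 4 higher and 10 lower, among the lower the VRAC list with LRRC8A in it. In the other splits of the libraries into 3 and 3, which mix the groups, 4 to 13 lists passed in the same way. With an estimated correlation 0 passed, and with fry 0 passed, the lowest fry adjusted p being 0.0635 for the basal-like list. At an unadjusted p under 0.05 the counts were 1 list with an estimated correlation and 9 lists with fry.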

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

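The setting without genes that hold GTGTCAC in the 3′ UTR, which keeps the fold changes of the main fit, was chosen after seeing the data. The other settings were planned. LRRC8A was lower with an adjusted p under 0.05 in each edgeR, DESeq2 and limma fit, at -0.95 to -0.86 on the log2 scale with 1 library left out, but does not reach an absolute log2 fold change of 1. In these fits 0 of its 4 partners passed. With 1 library left out, 246 to 504 genes changed, 92 to 212 higher and 154 to 306 lower, from 2 libraries against 3, and 10 to 15 lists passed camera. Of 118 followed genes that passed, 62 passed in all 6 of these fits and 2, CORO1A and KLK14, in 0. The 118 include the higher genes with the smallest p, some of them not named here, and this choice favours passing. None of the 118 changed direction in any setting that tested them.

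Limma on log2(FPKM + 1) called 182 genes (89 higher, 93 lower). A pseudocount of 0.1 gave 179 (87 and 92), 0.5 gave 181 (89 and 92), no filter gave 16 (8 and 8), and at least 5 FPKM gave 194 (102 and 92). Rescaling to an equal sum gave 174 (83 and 91), quantile normalization 193 (83 and 110), TMM factors 196 (77 and 119), and no trend 106 (51 and 55). Of the 182 genes, 165 were among the 590. DESeq2 called 660 genes, of which 556 were among the 590, and edgeR with DESeq2 size factors called 589 and with no filter 692. An adjusted p of 0.01 left 222 genes, and an absolute log2 fold change of at least 1 left 22. Without genes that hold the word, 452 genes changed, 151 of them higher. The cause was not tested for the lower counts with FPKM.

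With the replicate number as a block 671 genes changed, 547 of them among the 590, and 14 lists passed. The VRAC list lost its call under the block (camera adjusted p = 0.0588), and the fatty acid list gained one (0.0198). Deviations from the group means correlated across genes at 0.0277, -0.0890 and 0.00508 for equal numbers, and at -0.0961 to 0.0861 for unequal numbers. No sign of pairing by number was seen, but 3 libraries per group are too few to exclude it.

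On FPKM values, the integrin list passed in 7 of 9 settings (camera adjusted p 0.0265 to 0.0344), the fatty acid list in 8 of 9 (0.0233 to 0.0446), and the epithelial list on genes of at least 5 FPKM (0.0471). Of the 14 lists called, 0 passed with an estimated correlation and 0 with fry. With 1 library left out, the camera adjusted p of the list cholesterol and sterol synthesis was 0.000789 to 0.700, and its direction turned without control replicate 3 (0.700). That of the list mitochondrially encoded mRNAs was 0.00794 to 0.906, and its direction turned without LRRC8A shRNA replicate 3 (0.00794) and, with no call, without control replicate 2. The cause was not tested. In simulated data of this depth, spread and number of libraries, 30.9% of genes changed by 0.25 on the log2 scale were recovered; these limits were not varied singly. By expression in 4 equal groups of genes, the median SE was 0.273 in the lowest and 0.0466 in the highest, so few reads go with low precision, while at high counts other spread remains (FTL, SE 0.09).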

Other observations

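The gene families of the first paragraph were assembled after their values were seen, so no set test was run on them. The tests against shuffled gene values, the split of words by the base that follows and the setting without genes that hold the word were also chosen after the result was seen. Of 11 Wnt target genes tested, 4 fell and 7 did not pass. TCF7, a transcription factor of the pathway, fell by 0.45 (SE 0.05, edgeR adjusted p = 1.57e-05), the feedback inhibitor gene AXIN2 by 0.25 (SE 0.04, edgeR adjusted p = 0.00147), the receptor ligase gene RNF43 by 0.20 (SE 0.04) and APCDD1 by 0.54 (SE 0.12). TCF7, AXIN2 and RNF43 overlap other genes, so their counts are uncertain. Of 9 genes of the EGF receptor family and its ligands 3 fell, EGFR by 0.36 (SE 0.05, edgeR adjusted p = 0.000908) beside EREG and AREG. Of 8 mucin genes 2 fell, the gel-forming MUC5AC by 0.62 (SE 0.09) and MUC6 by 0.58 (SE 0.14). Of 9 kallikrein-related peptidase genes 3 fell, KLK7 by 0.34, KLK10 by 0.23 and KLK14 by 0.52. Of 6 metallothionein genes 3 fell, MT1X by 0.46, MT2A by 0.44 and MT1E by 0.46; these copies are nearly identical, so their counts are uncertain. Of the 6 fits that left out 1 library, KLK14 passed in 0 and MUC6 in 3 (edgeR adjusted p up to 0.171 and 0.126), APCDD1, KLK10 and MT1E in 4 and MT2A in 5.

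The 6 libraries can be split into 3 and 3 in 10 ways, so the share of splits with a result as large cannot fall under 0.1. In 1 of the 10, the real one, 590 genes changed, and the highest other split gave 3. Each other split has libraries of both groups on each side. A group difference then adds to its spread, which lowers the number of genes called, and in part remains in its fold changes. These splits are therefore not comparisons free of the group difference. By direction, the larger of the higher and lower counts was taken for each split, since the order of its groups is arbitrary. The highest other split gave 2 genes in that direction, against 240 higher and 350 lower in the real one, again 1 of the 10 for each. For gene lists called by camera the highest other split gave 13 against 14, again 1 of the 10. Every other split called lists, at least 4, while calling at most 3 genes. Camera with the preset correlation thus called lists also where the groups were mixed, so the number of lists hardly sets the real split apart.

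Of the 235 higher genes with an annotated 3′ UTR, among 240 higher in the LRRC8A shRNA libraries, 73 held the 7-base word GTGTCAC in the 3′ UTR (31.1%, 95% Wilson interval 25.5% to 37.2%) against 9.35% of genes not called and 8.14% of lower genes with such a UTR, shares that only describe a word picked from these genes. Against shuffled genes, the values argue against chance among 16357 words (permutation p = 0.001, the smallest 1000 shuffles can give). The shuffles, the matched draws and the SEs of the word count genes as independent and do not measure spread between libraries. The scan was not run on the other splits. From the mean of the 6 libraries, genes with the word were shifted against the rest by -0.0257, -0.00976 and -0.0123 in control replicates 1 to 3. In LRRC8A shRNA replicates 1 to 3 the shifts were 0.0107, 0.0151 and 0.0220. Sets matched on UTR length, GC content and expression reached a mean log2 fold change of at most 0.0241, against 0.0341 for genes with the word. This argues against these properties, but its permutation p = 0.0001, the smallest 10000 draws can give, does not count the picking of the word. The scan, which was adjusted for these properties, did count it. A source in 1 library is argued against by the smallest mean shift with a library left out, 0.0270 against 0.0319 with all, as differences of mean log2 CPM. A property of either strand is also argued against, since genes with the reverse complement GTGACAC were shifted by -0.0120. Repression of these transcripts in control cells by a small RNA that pairs with the word may account for the shift. In edgeR log2 fold changes, the shift was 0.0352 (SE 0.00667) for words in the 3′ UTR. It was 0.0114 (SE 0.00744) for words in coding or 5′ sequence alone. The word was picked by its 3′ UTR statistic, so this difference was favoured in advance and is no separate support. Words followed by A had a shift of 0.0584 (SE 0.0118) against 0.0243 (SE 0.00806) for others, a split chosen after the result was seen. Genes with at least 2 words exceeded those with 1 by 0.0219 (SE 0.0192, permutation p = 0.138), so repression by a small RNA stays open. The non-targeting hairpin and a small RNA of the cells that fell with LRRC8A cannot be told apart, since 0 libraries lack a hairpin.

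A seed match of the LRRC8A hairpin could lower genes in the same way. The lowest statistic of any word was -4.03 (permutation p = 0.297 against shuffled genes), which leaves this open, and direct effects of less LRRC8A were not separated from it, since 1 hairpin was used. Differences between the stable lines that do not come from LRRC8A were not separated either.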
